A study of Arabidopsis thaliana with 2 samples.

How the data were processed

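The series measured where the transcription factor ERF115 sat on chromatin in an Arabidopsis thaliana cell suspension. ERF115 belongs to the AP2/ERF family of plant transcription factors. It was expressed from the constitutive 35S promoter as a fusion to the HBH tag, which carries histidine stretches and a biotinylation site, in dark-grown PSB-D cells of the Landsberg erecta ecotype. Cells were harvested 2 days after subculturing and fixed with 0.75% formaldehyde for 10 minutes, per the labels' protocols. Protein-DNA complexes were then purified by tandem chromatin affinity purification on nickel and streptavidin beads and the recovered DNA was sequenced. Wild-type cells without the tagged protein went through the same purification as a mock. There was 1 ERF115-HBH library and 1 mock library.

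Per the submitters' processing notes, CASAVA 1.8.2, BWA 0.5.9, SAMtools 0.1.18, Picard and MACS 1.4.2 were used with the TAIR10 genome build. Those notes give no parameters, no order of steps and no filters. The deposited files are a peak list and an annotated copy of it, both for the ERF115-HBH sample. The authors' peak score is the value that MACS writes for each peak, which is 10 times the negative log10 of the peak's p-value. It was not normalised across libraries and was used only to describe, rank and filter peaks within this list. Per the file headers, the track name holds 2 library codes. Which of these was the control is not given in the sources used here, although the mock was described as the negative control in the series' design text. The authors also deposited a Z score per peak. It equalled the peak score minus the list mean, divided by the standard deviation of the list, and added no information. For each peak the annotated copy gives 1 locus, 1 location label (intergenic, UTR, coding or intron, each with 5' or 3'), 1 position inside the peak and, for some peaks, a mark. The rule behind the labels and the meaning of the mark are not given in the sources used here. The position lay inside the peak for 100% of peaks, a median of 209 bp from the midpoint, and was taken as the reference point of the peak. Read counts, sequencing depth and the mock library's own values were not analysed here, so the depth behind each peak is unknown.

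Loci were named with an NCBI RefSeq gene table of assembly TAIR10.1. Of the 608 loci assigned to peaks, 600 were in that table. Because the build names differ, no coordinate of the table was used. It served for names, for the order of neighbouring genes, for gene counts per chromosome and for the length of DNA between adjacent genes. All coordinates given are those of the deposited peaks, written 1-based. No genome sequence was used. The planned searches for the GCC-box and other motifs, distances to transcription start sites, and gene windows around start sites were therefore not run. In their place, the gene and the location label that the authors assigned to each peak were used. For locations the plan had named this substitute. For gene lists and name classes the assigned gene had been planned only as an alternative to start-site windows and became the main choice once no stranded annotation was at hand. Fold enrichment was not analysed either, so the planned naming of the peaks with the highest fold was dropped.

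The number of peaks per chromosome was compared with the number expected from the 27444 nuclear protein-coding genes of the table. The plan had foreseen chromosome length. The comparison used a Monte Carlo multinomial test with 100000 draws, followed by an exact binomial test per chromosome. Location shares carry Clopper-Pearson 95% intervals, which cover counting error only. The 12 gene lists, the keywords of 29 name classes, the test for lists and classes and the score thresholds were fixed before the data were examined. The search patterns that turned keywords into classes, and the use of gene number and of genes with a symbol as backgrounds, were set afterwards. The comparisons of 5' with 3' labels, of median scores, of marked with other peaks, of microRNA genes and of distances between genes with a peak were also chosen after the data had been seen. The lists hold 193 genes, of which 185 carried the intended symbol in the table. The other 8 are named by the table's symbol or by locus. Each list was compared with all other nuclear protein-coding genes by a two-sided Fisher's exact test with Benjamini-Hochberg adjustment over lists. For the name classes, the table held symbols and synonyms but no descriptions, so keywords were searched in those and the background was the 10374 protein-coding genes with a symbol. Median scores were compared by two-sided permutation tests with 100000 draws, adjusted over 4 comparisons. The genes named in the text are those of the peaks ranked 1 to 20 by score, every fixed-list member with a peak, and PSK5 and ERF115, with the assigned gene in place of the planned start-site window. The values of 1 list member with a peak are not reported here. Any other gene named was chosen after its values were seen, and this is stated.

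The tests were tried on simulated gene sets of the same size (564 genes with a peak among 27444). A list of 34 genes with a simulated odds ratio of 15 was called in 100% of 200 simulations, one of 5 in 65%, and one with no effect in 6%. For a list of 10 genes the shares were 75%, 23% and 1%. For these lists a call was an unadjusted p under 0.05 by Fisher's exact test. That rule is looser than the adjusted p used in the results, so the shares overstate what the latter would call. With the weight of chromosome 3 raised 1.4-fold, the test over all 5 chromosomes called 79.5% of simulations, and an even spread 4%. The weights were then rescaled, so the simulated ratio to the expected count was under 1.4. The exact binomial test per chromosome was not tried. Simulated peaks were drawn independently of each other, so the 4% does not cover peaks that lie close together. Planting 60 neighbouring pairs was called in 100% and none planted in 1%, by the count of neighbouring pairs within 5 genes. On that count the data held 97 pairs against a median of 58 in random draws. The counts of pairs by distance in the closing section were not tried on simulations. For the closing section, some tests of explanations were replaced after their first results had been seen, and both versions are given there. Analyses used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, SciPy 1.17.1 and statsmodels 0.14.6. Figures were drawn with matplotlib 3.10.9. With 1 library per group there is no replicate check of any peak. The p-values describe this single peak list and not the variation between cultures.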

Results

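To find genes bound by ERF115, chromatin recovered with the tagged protein was sequenced beside a mock purification from wild-type cells. The series title links degradation of ERF115 and signalling by phytosulfokine, a sulfated peptide hormone, to cell division in the root quiescent centre. The tests of 5' against 3' labels, of median scores and of marked peaks were chosen after the data had been seen. The deposited list held 612 ERF115-HBH peaks on the 5 nuclear chromosomes and none on the organelle genomes. Peaks were broad, with a median width of 1894 bp (quartiles 1372 and 2901 bp), and together covered 1450 kb. Peak scores ran from 50.01 to 537.85 with a median of 78.9, and 192 peaks scored at least 100. The peaks were assigned to 608 loci, of which 564 were nuclear protein-coding genes, or 2.06% of all such genes.

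The first question was where the peaks lay relative to genes. Most carried an intergenic label: 392 of 612 peaks (64.1%, 95% interval 60.1 to 67.9%). Each peak has 1 label, so a broad peak labelled intergenic may still overlap a gene. The most frequent label was intergenic 5', with 275 peaks or 44.9% (40.9 to 49.0%). It is read here as the upstream side of the assigned gene, which was not checked against gene strand. Intergenic 3' followed with 117 peaks or 19.1% (16.1 to 22.5%). Among intergenic peaks 70.2% (65.4 to 74.6%) carried the 5' label, which departed from an equal split (exact binomial test, adjusted p = 3.58e-15). UTR peaks leaned the same way, with 49 in 5' and 23 in 3' UTRs (exact binomial test, adjusted p = 0.00589). Coding peaks did not, with 62 labelled 5' and 64 labelled 3' (49.2%, 40.2 to 58.3%, exact binomial test, adjusted p = 0.929). The 5' share differed between intergenic and coding peaks (Fisher's exact test, p = 2.60e-05). For intron peaks, 13 with a 5' and 9 with a 3' label, no departure was detectable (exact binomial test, adjusted p = 0.698). An equal split is not what random placement in the genome would give, because upstream and downstream intergenic stretches need not be equally long. Peaks with 5' labels were not distinguishable from those with 3' labels in score, with medians of 78.9 and 79.6 (permutation test, adjusted p = 0.833).

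**Figure D1:**
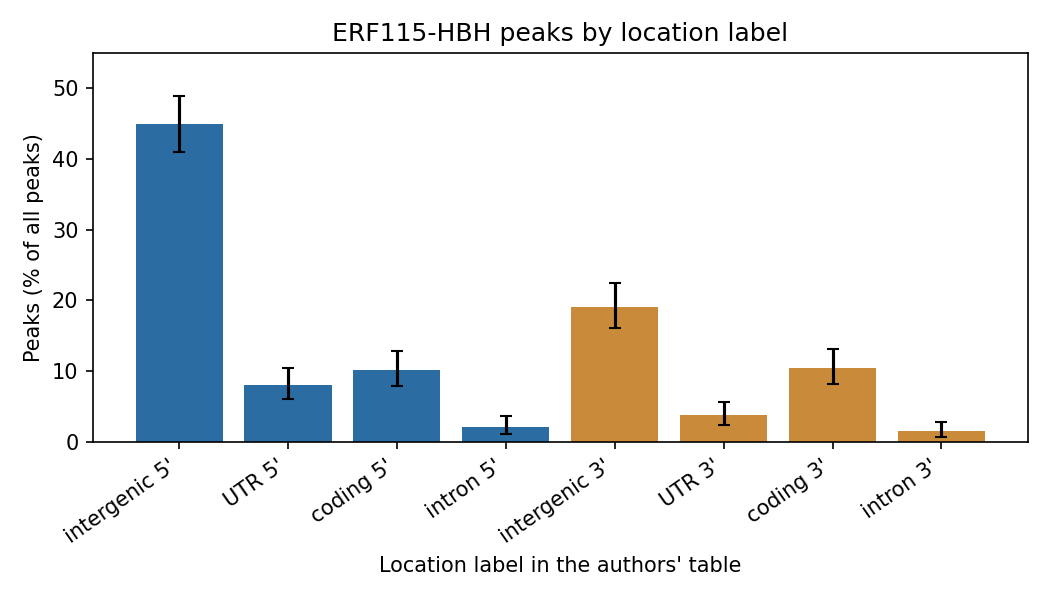
Share of the 612 ERF115-HBH peaks (y axis, %) with each location label of the authors' table (x axis), 5' labels in blue and 3' labels in orange; error bars are Clopper-Pearson 95% intervals. Intergenic 5' is the most frequent label at 44.9%, against 19.1% for intergenic 3', while coding 5' and coding 3' are close to each other.

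The peaks with the highest scores lay next to genes of several kinds, among them 3 WRKY transcription factors, a family known for roles in defence and stress responses. The peak with the highest score, 537.85, lay at chromosome 5, 20109979 to 20112455, intergenic 5' of AT5G49560. The next, with a score of 473.14, lay at chromosome 2, 18485473 to 18490271, intergenic 3' of AT2G44820. The third, with a score of 440.95, lay at chromosome 3, 9869684 to 9871162, and was labelled coding 3' in AFB2 (AT3G26810), which encodes an auxin receptor F-box protein. WRKY60 (AT2G25000, score 310.2), WRKY18 (AT4G31800, score 297.48) and WRKY26 (AT5G07100, score 287.33) ranked 8, 10 and 12, each with an intergenic 5' peak. Other genes with a symbol among these 20 peaks were ABCG43, a member of the ABC transporter family with a score of 308.32, and emb2737 with a score of 314.2. WAVH1 followed with 290.37 and SSE1, a peroxin, with 283.51. The remaining loci, in order of score, were AT3G52470, AT5G49665, AT2G33690, AT4G37480, AT3G24120, AT5G03870, AT3G60480, AT5G61880, AT5G49700 and AT3G19870, with scores from 371.99 down to 252.0. Of the 20 peaks, 9 were labelled intergenic 5' and 7 carried a label within a gene. The peaks of AT5G49665, at 20166197 to 20172350, and AT5G49700, at 20189485 to 20196040, lie near that of AT5G49560 on chromosome 5, so 3 of the 20 came from a single region.

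The link to phytosulfokine was examined with a list of 11 genes for its precursors, receptors and processing enzyme and the related PSY peptide pathway. PSK5 (AT5G65870), which encodes a phytosulfokine precursor, had a peak at chromosome 5, 26350073 to 26351359, labelled intergenic 5'. Its score was 59.13, rank 483 of 612. It was the only member of the list with a peak, against 0.226 expected, and the list did not pass the test (odds ratio 4.77, 95% interval 0.110 to 33.6, Fisher's exact test, adjusted p = 0.613). ERF115 itself (AT5G07310) had no peak. None of the 8 genes of the ERF115 subgroup was assigned one, with 0.164 expected.

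Of the 12 lists, that of other AP2/ERF transcription factors was the one past the adjusted threshold. It is a selection fixed in advance and leaves out part of the family, for example AT5G51190 (ERF105). That gene, named after its values were seen, had an intergenic 5' peak with a score of 101.34. Of the list's 34 members 9 had a peak, against 0.699 expected (odds ratio 17.4, 95% interval 7.12 to 38.8, Fisher's exact test, adjusted p = 2.44e-07). They were ERF1 (AT3G23240, chromosome 3, 8292467 to 8297152), a regulator of ethylene and jasmonate defence genes, ERF-1 (AT4G17500), ERF5 (AT5G47230), ERF6 (AT4G17490), ERF10 (AT1G03800), ERF12 (AT1G28360), the cold-response regulator CBF1 (AT4G25490), RAP2.4 (AT1G78080) and CEJ1 (AT3G50260). CEJ1, also called DEAR1, had 2 peaks, at chromosome 3, 18632252 to 18633733 and 18634157 to 18635804. Of the 10 peaks at these genes 5 were intergenic 5', 4 were coding 3' and 1 was in a 3' UTR. Their scores ran from 50.74 at CBF1, close to the minimum of 50.01 over all peaks, to 139.6 at ERF12. None was among the 20 highest. The median score of 70.5 at these genes was not distinguishable from 79.4 at all other peaks (permutation test, adjusted p = 0.833). The call was lost at higher score thresholds, where fewer genes had a peak. Among the 306 peaks with the highest scores 3 members were left against 0.353 expected, which no longer passed (Fisher's exact test, adjusted p = 0.0540), and among peaks scoring at least 100 there were 2 against 0.223 (adjusted p = 0.251).

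Genes of hormone pathways and the cell cycle had single peaks that did not pass as groups. In ethylene synthesis and signalling 2 of 14 genes had one, against 0.288 expected (Fisher's exact test, p = 0.0326, adjusted p = 0.195). ACS2 (AT1G01480), an ACC synthase of ethylene synthesis, had an intergenic 5' peak with a score of 110.85. In the jasmonate list, 1 of 17 genes had a peak: the signalling repressor JAZ8 (AT1G30135), intergenic 5', with a score of 117.75. In the brassinosteroid list it was 1 of 11, the receptor BRL3 (AT3G13380), in the 5' UTR with a score of 59.06. In the cell cycle list it was 1 of 35, the inhibitor LGO (AT3G10525, also called SMR1), intergenic 3' with a score of 51.94. Their adjusted p-values by Fisher's exact test were 0.714, 0.613 and 1. No peak was assigned to any of 18 root stem cell niche genes, 18 auxin genes, 5 GRAS factors related to PAT1, 10 rapid stress and touch genes or 12 photosynthesis genes. The last served as a control list for dark-grown cells. These 5 lists and the ERF115 subgroup hold 71 genes with 1.46 genes expected, so the absence of peaks does not separate them from other genes. A setting chosen after seeing the data also counted genes adjacent, in the order of protein-coding genes, to one with a peak. With it the niche list had 3 genes against 1.07 expected. They were WOX5, MYB56 and RBR1, named after their values were seen. The ERF115 subgroup had 2 against 0.474, and neither passed (Fisher's exact test, adjusted p = 0.262 for each). The rapid list had 1 against 0.593, and the auxin, GRAS and photosynthesis lists had none.

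Among the 29 name classes, WRKY genes were the class past the threshold. Of 72 members 7 had a peak, against 1.74 expected (odds ratio 4.44, 95% interval 1.70 to 9.81, Fisher's exact test, adjusted p = 0.04998). Beside the 3 genes above they were WRKY66 (score 181.83), WRKY57 (score 133.98), WRKY15 (score 125.44) and WRKY6 (score 60.6), named after their values were seen. Among peaks scoring at least 100 there were 6 WRKY genes against 0.479 expected (Fisher's exact test, adjusted p = 0.000223). Expansins, proteins that loosen cell walls, had peaks at 4 of 36 genes, against 0.871 expected, and did not pass (p = 0.0107, adjusted p = 0.116 by Fisher's exact test). These were EXPA8 (score 191.95), EXP3 (score 118.02), EXPA4 (score 64.27) and EXPB3 (score 52.72), also named after their values were seen. Genes with ethylene in a name, 5 of 57 with 1.38 expected, had the same adjusted p of 0.116 and all 5 were AP2/ERF genes of the list above. Genes with auxin in a name had peaks at 3 of 76, against 1.84 expected, and did not pass (Fisher's exact test, adjusted p = 0.790). Among them was AFB2, named above, which the fixed auxin list does not hold. MYB genes, 3 of 143 with 3.46 expected, and NAC genes, 4 of 100 with 2.42 expected, did not depart from other genes (Fisher's exact test, adjusted p = 1 and 0.753). Of the 29 classes 3 had an unadjusted p under 0.05, namely WRKY, expansin and ethylene, and 6 had no gene with a peak among genes with a symbol. Genes known only by a synonym were not counted. Examples with a peak, named after their values were seen, were the peroxidases AT5G64120 (score 166.88) and AT2G41480 (score 159.59). AT5G41920, also called SCARECROW-LIKE 23, had a score of 63.75. The empty peroxidase and GRAS or scarecrow classes are therefore not a lack of peaks at such genes.

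**Figure D2:**
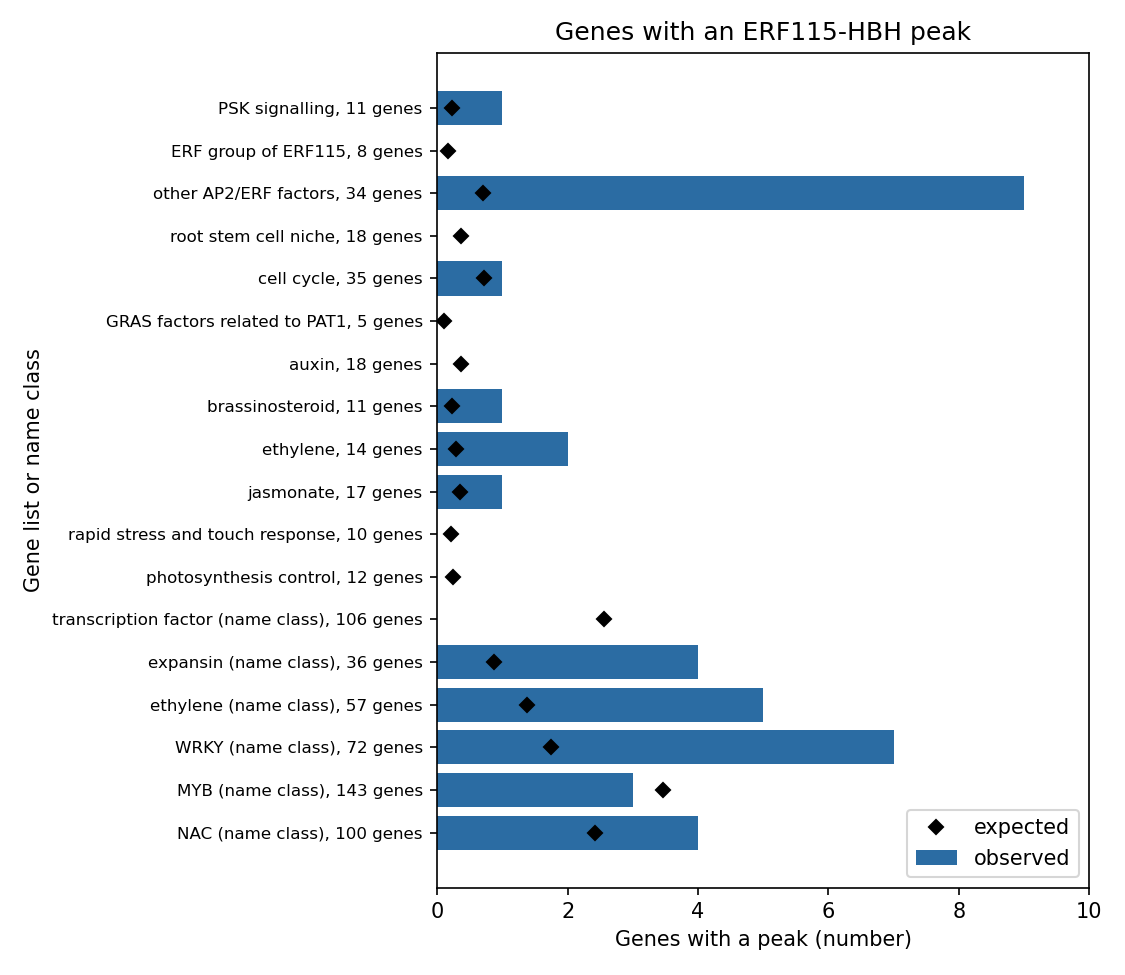
Number of genes with an ERF115-HBH peak (x axis) in each fixed gene list and in 6 of the name classes (y axis, with the number of genes); bars are the observed numbers and diamonds the numbers expected from all genes of the background. The AP2/ERF list reaches 9 against 0.699 expected and the WRKY class 7 against 1.74. The transcription factor class, 0 of 106 genes against 2.56, holds only genes with that phrase in a symbol or synonym. The WRKY and ERF genes with a peak are not in it.

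The peaks were not spread over the chromosomes in proportion to genes (Monte Carlo version of the exact multinomial test, 100000 draws, p = 2.00e-05). Chromosome 3 held 172 peaks against 121.8 expected, a ratio of 1.41 (95% interval 1.24 to 1.60, exact binomial test, adjusted p = 5.31e-06). Chromosome 2 held 76 peaks at a ratio of 0.789 and chromosome 4 held 74 at a ratio of 0.794. Neither passed the exact binomial test (adjusted p = 0.0539 for each), a call that changed with the setting. Chromosome 4 passed among the 306 peaks with the highest scores (28 peaks, ratio 0.601, adjusted p = 0.00635 by the exact test). With expectation from the span of the peaks, chosen after seeing the data, chromosomes 2 and 4 both passed (exact binomial test, adjusted p = 0.0136 and 0.0473). The lower count on chromosome 2 was not kept at higher scores, with ratios of 0.956 among the 306 peaks and 1.09 among those scoring at least 100. Chromosomes 1 and 5 had 143 and 147 peaks, at ratios of 0.896 and 1.04 (exact binomial test, adjusted p = 0.161 and 0.565). The median score on chromosome 3, 77.8, was not distinguishable from the 79.6 on the other chromosomes (permutation test, adjusted p = 0.833). Peaks near each other are not independent, so these intervals are too narrow.

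**Figure D3:**
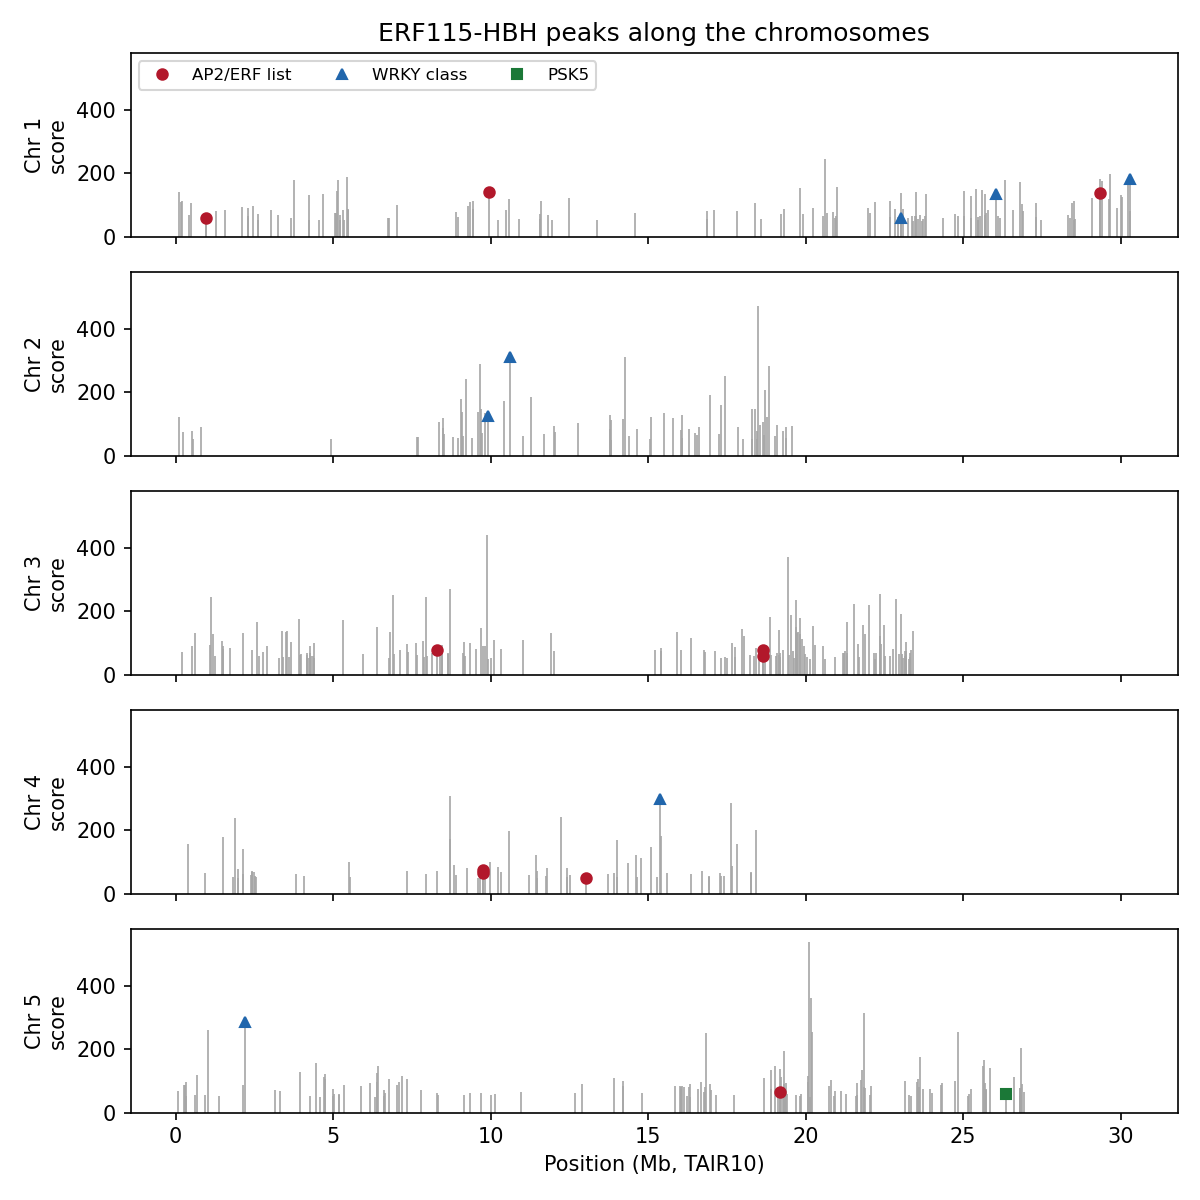
Position (x axis, Mb, TAIR10) and score (y axis) of each ERF115-HBH peak on the 5 chromosomes, 1 panel each, as grey lines; red circles are peaks at AP2/ERF list genes, blue triangles peaks at WRKY genes and the green square the PSK5 peak. Chromosome 3 holds 172 peaks, and the 3 WRKY peaks with scores of 287.33 and above stand over the peaks of the AP2/ERF list, whose highest score is 139.6.

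The mark TP stands beside 22 peaks at 21 loci in the authors' deposited table, in a column headed DE, whose meaning is not given in the sources used here. The PSK5 peak and both CEJ1 peaks are among them, as are the peaks at AT3G24120 and AT5G49700. Other marked genes with a symbol, named after their values were seen, were EXP3, UGT73D1, TGA4, LBD38, ARA12 and PAHX. The intergenic 5' label was more frequent among the marked peaks, at 15 of 22 (68.2%), than among the others, at 260 of 590 (44.1%) (Fisher's exact test, p = 0.0295, not adjusted). The marked peaks had a median score of 84.1 in the authors' deposited table, not distinguishable from 78.9 for the rest (permutation test, adjusted p = 0.833).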

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

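Alternatives chosen after seeing the data were the 5' UTR, peak span, 20 kb, 5' label, adjacent gene and background ones. With 1 library per group, no replicate could be left out. No paired analysis was possible because each group holds 1 library. The share of peaks labelled intergenic 5', 44.9%, was 44.1% among the 306 peaks with the highest scores and 43.8% among those scoring at least 100. Adding 5' UTR peaks moved it to 52.9%. The ratio for chromosome 3, 1.41, stayed between 1.36 and 1.43 and past the threshold under both score thresholds, with expectation from the span of the peaks, and with peaks under 20 kb apart counted once. The lower counts on chromosomes 2 and 4, not called, passed under some of these: chromosome 4 among the 306 peaks and both with the span (exact binomial test, adjusted p = 0.00635, 0.0136 and 0.0473), and neither among peaks scoring at least 100 or with peaks counted once. For chromosome 2 the ratio was 0.956 among the 306 peaks and turned to 1.09 among peaks scoring at least 100. The number of gene lists past the threshold, 1, fell to 0 among the 306 peaks (2 lists at an unadjusted p under 0.05) and to 0 among peaks scoring at least 100 (1 list), both by Fisher's exact test. Both thresholds lowered the number of genes with a peak. The AP2/ERF list kept its call with only 5' labelled peaks (5 members against 0.463 expected, Fisher's exact test, adjusted p = 0.00110) and with adjacent genes counted (12 against 2.02, adjusted p = 3.51e-06). Its odds ratio of 17.4 fell to 12.6 and 8.71 under these and to 9.31 and 9.56 under the score thresholds. The PSK list, not called, fell to an odds ratio of 0 under each score threshold because PSK5 dropped out. The number of name classes past the threshold, 1, became 2 with all protein-coding genes as background, where ethylene names joined WRKY (7 genes, Fisher's exact test, adjusted p = 0.00722). The odds ratio of ethylene names fell to 0 among peaks scoring at least 100. The WRKY class passed under every alternative run (adjusted p from 0.000223 to 0.0382), although its main value lay at the threshold. Not run for lack of a genome sequence or an annotation with strand were the alternatives for motifs, start-site windows, nearest start site, the reference point and the pericentromere. Those for FDR and fold enrichment were not run because the files used here give neither. Unknown depth limits what the lack of a peak can show.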

Other observations

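Apart from the planned test of gibberellin names, the tests in this part were chosen after the data had been seen. For flanking length, neighbouring family copies and the first versions of 3 others the prediction was written before the test was run. Among loci that do not encode proteins, 4 microRNA genes were assigned peaks, named here after their values were seen. MIR168a, which targets the small-RNA effector ARGONAUTE1, had the highest score of these, 197.98, at chromosome 4, 10575807 to 10579018, intergenic 5'. MIR158a (score 138.16) and MIR161 (score 82.18) also had intergenic 5' peaks, and MIR391 (score 87.58) an intergenic 3' peak. The number did not depart detectably from the 5.16 expected of 326 microRNA genes in the names table (Fisher's exact test, p = 0.823, adjusted over 4 gene types p = 0.823). The other types tested had fewer loci with a peak than expected: pseudogenes 20 against 62.0 (adjusted p = 2.57e-10), long non-coding RNA genes 4 against 55.1 (adjusted p = 2.72e-19) and tRNA genes 1 against 9.89 (adjusted p = 0.00128), all by Fisher's exact test. The set of genes open to assignment of a peak is not given in the sources used here, so these counts are not read as differences in binding. Of the 19 genes with gibberellin in a name 2 had a peak, against 0.460 expected (adjusted p = 0.442, Fisher's exact test). They are named here after their values were seen. GAI, a DELLA repressor, had an intergenic 3' peak with a score of 180.56. GA2OX6, a gibberellin-inactivating enzyme, had an intergenic 5' peak with a score of 106.81. RGL1 (RGA-like 1), also named after its values were seen, lacks the keyword and was not counted. It had an intergenic 5' peak with a score of 72.94.

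The 9 genes of the AP2/ERF list with a peak were weighed first. Long intergenic DNA around these genes is argued against as the whole cause, since 10000 random draws matched on flanking intergenic length gave 0.905 genes on average and 6 at most (permutation test, one-sided p = 0.0001, the smallest the draws can give). Neighbouring family copies counted separately are argued against too as the whole cause. Merging members within 2 genes of each other left 8 of 29 units against 0.595 expected (Fisher's exact test, p = 8.78e-08). Each peak was assigned to 1 gene, so a single peak shared by copies could not have raised the count in any case. Recovery of rapidly induced genes in general stays open. Of 10 rapid stress and touch genes 0 had a peak, which was not distinguishable from the AP2/ERF share (Fisher's exact test, p = 0.0923). A count of 0 is the lowest possible, so a list of 10 genes could not have argued against this explanation. Binding of ERF115 to regulatory DNA of its own family also stays open as a hypothesis that was not tested, and the call itself was lost at higher score thresholds (adjusted p = 0.0540 and 0.251, Fisher's exact test).

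Some high peaks were assigned to a gene beside or near an AP2/ERF gene. A candidate explanation for list members without a peak is that each peak was given to a single gene. AT5G61880, with a score of 254.42, is adjacent to AT5G61890, a member of the ERF115 subgroup. AT2G44820, with a score of 473.14, lies 2 protein-coding genes from ERF13, which is therefore not among the adjacent genes counted next. The AP2/ERF list and the ERF115 subgroup hold 33 genes without a peak. Of these, 5 were adjacent, in the order of protein-coding genes, to a gene with one, against 1.31 expected (Fisher's exact test, p = 0.00905). They were ERF8, ERF11, DREB1A, Rap2.6L and AT5G61890, named after their values were seen. Peaks at other kinds of loci were not counted. An example, also named after its values were seen, is the pseudogene AT5G47225 (score 138.02), between ERF2 and ERF5 by locus number. Without ERF11 and DREB1A, which neighbour list members with a peak, 3 of 31 remained against 1.22 expected (Fisher's exact test, p = 0.122). The hypothesis stays open, since leaving out these copies was decided after the first value was seen.

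Peaks were in excess on chromosome 3, with 60 genes in its first part by gene order and 101 in its second, each against 56.1 expected. The first part, at a ratio of 1.07, lay above the first parts of chromosomes 1, 2, 4 and 5 (0.721, 0.609, 0.745 and 0.723). The second part of chromosome 3 likewise lay above the second parts of those chromosomes (1.09, 0.992, 0.815 and 1.31). The excess was therefore not limited to the second part. A few dense regions are argued against as the whole cause, since permuting whole blocks of 100 genes between chromosomes left the difference (2.91 against 1.84 peaks assigned to protein-coding genes per block, medians 3 and 2, permutation p = 0.00019). It also stood with the densest 10% of blocks left out of each side (2.396 against 1.434, permutation p = 9.00e-05) and with blocks of 300 genes (8.72 against 5.46, permutation p = 0.00338). Gain of the whole chromosome in the culture stays open, because the unequal split of chromosome 3 (exact binomial p = 0.00154) would count against it only if other chromosomes split equally, and chromosomes 1 and 5 did not (p = 0.0238 and 0.00120). No biological explanation was tested.

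Genes with a peak lay close together in gene order, with 68 pairs 1 to 3 genes apart against a median of 36 in 10000 random draws per chromosome (permutation p = 0.0002, the smallest the draws can give). Broad enriched stretches split into several peaks are argued against as the whole cause by 126 pairs 4 to 10 genes apart, above the central 95% of draws (67 to 103). They may still add to the closest pairs. Differences over regions of about 100 genes are consistent with 1034 pairs 31 to 100 genes apart, against 784 to 895 in the draws. Whether such regions follow chromatin state or copy number was not tested, and no biological explanation was.

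For dense regions and both explanations of close pairs, the test first written gave another outcome than the later one, and the replacement was made after that outcome was seen. For dense regions, merging peaks under 100 kb apart left 64 regions on chromosome 3 against 56.3 expected (exact binomial test, adjusted p = 0.657), which would have spoken for the explanation. That merging decides nothing, because an excess spread evenly along chromosome 3 passed it in 1.1% of 1000 simulations. For split stretches, merging peaks under 10 kb apart left 46 neighbouring pairs within 5 genes, inside the range of the draws (36 to 61), which would have spoken for the explanation. For regional differences, keeping 1 peak per 100 kb gave a variance to mean ratio per 100 genes of 0.545, under the range of the draws (0.829 to 1.16), which would have spoken against it. In both, peaks had been merged in the data but not in the draws, so that close neighbours were removed from one side of the comparison. In the later versions data and draws were merged alike, but the units changed too. For split stretches, genes with a peak up to 3 genes apart were merged, and pairs were counted within 10 genes. This gave 91 neighbouring pairs against 58 to 87. For regional differences, runs at the gene spacing of 100 kb were merged, and the ratio was 0.574 against 0.416 to 0.564. Both values lay just above their ranges, so the readings on close pairs rest on a small margin. The changed outcomes cannot be credited to merging alike only. The test of a chromosome gain was first read as evidence against it, and that reading was withdrawn after the splits of the other chromosomes had been computed.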
